A study of Mus musculus with 20 samples.

How the data were processed

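RNA from brain hemispheres of male C57BL/6 mice was prepared with the TruSeq RNA v2 kit, which keeps no strand information, so reads of overlapping genes on opposite strands are not separated. The 20 samples were grouped by the age and perturbation labels into 4 groups of 5. The titles of the older animals carry the number 24, while the age label and the series design give 20 months, and the labels were followed. Nothing in the labels says whether the samples are separate animals, so p-values measure variation between samples as deposited. No label gives a batch, a sequencing date or a pairing. The titles number the ages in separate ranges, and treadmill animals and controls in separate runs within each age. A cohort or processing difference that followed these ranges cannot be told apart from age or from treadmill exercise.

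Per the submitters' processing notes, reads were converted with bcl2fastq 1.8.2, mapped with STAR 2.4.1d to the GRCm38 build and counted per gene with featureCounts 1.4.6-p4. The release of the gene annotation is not given in the sources used here. The deposited count table holds whole numbers of reads per gene in the unit count, with 47729 gene IDs and 20 columns. A second deposited table of the same size, named RPKM by the authors, was treated as a score, since its values were not reads scaled by the total of their own library. In a solution over 8064 genes, its divisors repeated every 40 genes down the table and shifted by 9 per column. Of the 40 divisors, 20 matched the library totals in column order within 0.1% (largest deviation 0.000114%), and the other 20 were not compared with the totals. The residual was 3.3e-05 natural log units with these divisors and 0.342 with each library's own total. A share of 2.5% of the values was divided by the own library total, and the median absolute error against it was 0.274 log2 units, with a largest of 1.58. Tests therefore used the counts, and the score table entered only as an alternative, with 20360 genes after its filter.

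Symbols, biotypes and coordinates came from GENCODE M21 on GRCm38, in which 47310 of the IDs were found and 419 were not. Analysis used R 4.3.3. Genes were filtered with filterByExpr by group, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, robust) in 1 fit of 4 groups, which left 17379 genes. TMM factors were 0.983 to 1.032. The 6 comparisons were treadmill against control at each age, 20 against 5 months in controls and in treadmill animals, the difference of the treadmill effects between ages, and the treadmill effect averaged over ages. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Confidence intervals are at 95%. With total counts of 22372334 to 57625169 per library, intervals and standard errors cover variation between samples and counting error.

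Gene lists were 51 sets of cell type markers, brain regions and pathways, and the 48 with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The test was repeated with a correlation estimated for each list. Members passing were counted over all genes tested and adjusted over the list alone. Composition of the libraries (total counts, genes detected and the shares of mitochondrially encoded, hemoglobin and the 10 most abundant genes) was compared with two-sided exact permutation tests over the 252 splits of 5 and 5 libraries, whose smallest p is 0.0079. Correlations of effects across genes were compared with permuted labels. The age effect and the treadmill effect at 20 months were taken from different controls, since a shared control group biases their correlation below 0.

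Named genes followed a rule. It took the 8 genes with the smallest p in each direction for the 3 main comparisons (treadmill at each age, age in controls), 4 in each direction for the others, the 5 with the smallest p where none passed, and 2 members of each list that passed in a main comparison. Bdnf, Igf1, Vegfa, Gfap, C4b, Fos, Arc, Dcx, Ttr and Xist were always given. Gene models without a proper symbol and pseudogenes were counted and not named, except Clec7a, whose annotation as a polymorphic pseudogene was read as a gene. Not every gene that the rule took is reported, and those left out were not replaced and enter no count over named genes. Groups, comparisons, tests, lists, this rule and the other settings of the next paragraph were chosen before the data were examined. Chosen afterwards were the fits without 2 control libraries that stood apart, the cerebellum covariate, the exact permutation test of list means, the count of genes without overlap between groups, the fold intervals of the genes always given and the summary and the permutation test of the protocadherin clusters. So were the splits of the libraries for age and for treadmill at each age. The tests of depth, unspliced RNA, treadmill exercise on the cerebellum list, microglia and blood were also chosen afterwards.

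The other settings were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a stricter filter (above 1 CPM in 5 libraries), only the groups compared, 1 surrogate variable (sva 3.50.0) and the choroid plexus list mean as covariates, and leaving out each library in turn. The score table was tested with limma on log2 values with a pseudocount of 0.1 and a minimum mean of 0.1, with a pseudocount of 1, and without the minimum. Correlations were repeated with a prior count of 5, with shared controls and with other sets of genes. The steps were tested on simulated data, with 200 genes changed in the comparison of treadmill at 20 months. Of 50 genes each, 46%, 72%, 96% and 98% were recovered at 1.25, 1.5, 2 and 3-fold changes, and 10 of 166 calls were false. Of the unchanged genes 4.73% had an unadjusted p under 0.05, and camera called the shifted list and 0 others. The simulated genes varied independently of each other, so this cannot show how many lists are called falsely in real libraries. There, other splits of the libraries for treadmill at 20 months gave up to 21 lists. All pairs within a group differed by more than counting error (chi-square per degree of freedom 2.07 to 36.1 over 40 pairs), so no library was a copy of another of its group. Pairs between groups were not examined in this way. All 20 libraries were kept.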

Results

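RNA was sequenced from brain hemispheres of male C57BL/6 mice, an inbred laboratory strain, in 20 libraries. They fell into 4 groups of 5, controls and treadmill animals at 5 months and controls and treadmill animals at 20 months. The treadmill groups had physical exercise per the labels, and its length and intensity are not given in the sources used here. The comparisons address which genes differ in the brain with exercise at each age, and which differ between the ages. Total counts were 26711022, 25132102, 23513579, 28168750 and 26038063 in 5 months controls 1 to 5, and 40580481, 43165983, 22372334, 22682328 and 23289253 in 5 months treadmill animals 1 to 5. They were 57625169, 26673186, 24992437, 35294190 and 24448244 in 20 months controls 1 to 5, and 39627226, 26884996, 26039475, 26855603 and 23270207 in 20 months treadmill animals 1 to 5. Between 23489 and 26639 genes had at least 1 count in a library. Xist, the RNA of the inactive X chromosome, had 0 to 13 counts per library and was not tested, and Y-linked genes had 3098 to 7974 counts.

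The first principal component set 2 control libraries apart, and the second parted the ages. Over the 17379 genes tested, the correlation of log2 CPM (counts scaled to a common library size) was 0.989 to 0.996 across genes for the 40 pairs of libraries within a group, and 0.986 to 0.997 for the 150 pairs between groups, a measure that mostly reflects the range of expression across genes. The first component held 19% of the variance and set 5 months control 1 (32.8) and 20 months control 5 (39.9) apart from the other 18 libraries, of which 5 months treadmill 5 came next at 11.4. The second component held 13.4% of the variance and parted the ages, with -16.1 to -5.6 in the 5 months libraries and 2.7 to 24.2 in the 20 months libraries. Means are given below with the SD of 5 libraries per group, and log2 fold changes with their standard error.

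**Figure D1:**
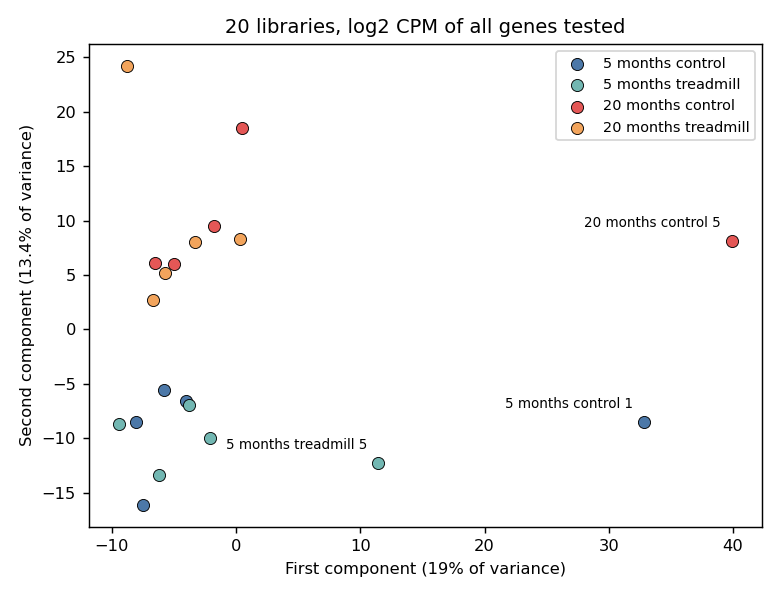
Each point is a library placed by its first and second principal components, computed from log2 CPM of the 17379 genes tested, with the color giving its group. The first component (19% of the variance) sets 5 months control 1 and 20 months control 5 apart, and the second (13.4%) runs from the 5 months libraries (-16.1 to -5.6) to the 20 months libraries (2.7 to 24.2).

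In control animals, the complement genes C4b and C3 and the myeloid receptor gene Clec7a were higher at 20 months than at 5 months, and the receptor gene Gpr17 was lower. C4b, which encodes complement component C4, rose 2.5-fold from 31.5 ± 3.89 to 78.9 ± 21.9 CPM (SD, n = 5; edgeR adjusted p = 0.0025). C3, the complement component on which the activation pathways converge, rose 2.35-fold from 2.68 ± 0.234 to 6.3 ± 1.42 CPM (adjusted p = 0.00069). Clec7a, the receptor dectin-1 of myeloid cells, rose 3.83-fold from 0.443 ± 0.061 to 1.76 ± 0.764 CPM (adjusted p = 0.0023). Gpr17, a receptor of committed oligodendrocyte precursors, fell from 55.6 ± 4.38 to 31.7 ± 4.15 CPM (0.57-fold, adjusted p = 0.0023). In each of these 4 genes all 5 older libraries lay beyond all 5 younger ones. On the GRCm38 build, C4b (ENSMUSG00000073418) lies on chromosome 17 at 34728380 to 34743882, C3 (ENSMUSG00000024164) on chromosome 17 at 57203970 to 57228136, Clec7a (ENSMUSG00000079293) on chromosome 6 at 129461591 to 129472779 and Gpr17 (ENSMUSG00000052229) on chromosome 18 at 31942997 to 31949636. Reads of C4b may be shared with its paralog C4a, Gpr17 overlaps Lims2 on the other strand in these unstranded libraries, and the annotation lists Clec7a as a polymorphic pseudogene.

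In all, 63 genes rose and 21 fell with age in controls (84 genes; 55 and 19 of them with a proper symbol). At an unadjusted p under 0.05 there were 1772 genes, which 32 of 100 splits of the same libraries, the real one included, reached (median of the other splits 741). In 73 of the 84 genes all older libraries lay beyond all younger ones. Chance gives this in 0.794% of unselected genes, and it held for 2.28% of the genes tested. The called genes were selected by p on the same libraries, so their separation, named genes included, is no independent support. DESeq2 called 162 genes and limma-voom 76. The edgeR count was 47 without 5 months control 4, 51 without 20 months control 3, 30 with only the groups compared in the fit and 391 with 1 surrogate variable. From the deposited values named RPKM, whose divisors are described under the processing of the data, limma called 3 genes, and of the 35 named age calls 32 ended and 2 turned sign. With only the groups compared, 13 named calls in controls ended, namely Hapln2 (adjusted p = 0.06), Itgax and Tlr2 (0.078 each), Aplnr (0.094), Ctss (0.1), Ypel1 (0.11), Col1a2 and Il33 (0.12 each), Sox11 (0.14), Dpysl3 and Hsph1 (0.17 each), Col3a1 (0.21) and Ifit3 (0.27). Without the 2 control libraries apart on the first component, the calls of Col1a2 (0.054), Il33 (0.069), Col3a1 (0.079), Ifit3 (0.093) and Hsph1 (0.12) ended. In all 27 named calls but that of Ifit3 (4 of 5), all 5 older libraries lay beyond all younger ones.

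The genes with the smallest p were led by Pcdhb9, a clustered protocadherin of neuronal cell contacts, which rose from 13.4 ± 1.11 to 23.2 ± 1.35 CPM (log2 fold change 0.80 ± 0.07, adjusted p = 1.9e-07). It lies on chromosome 18 at 37400855 to 37403909 (ENSMUSG00000051242). Its neighbors Pcdhb6 (0.89 ± 0.13), Pcdhb3 (0.52 ± 0.07) and Pcdhb14 (0.49 ± 0.07) also rose, and reads of these similar genes may be shared. Spag6, a protein of the axoneme of motile cilia, rose by 0.96 ± 0.11 (adjusted p = 2.4e-05). Mpeg1, a pore-forming protein of macrophages, rose by 0.45 ± 0.06, and Cd22, a sialic acid-binding receptor of B cells and microglia, by 1.46 ± 0.22 from 0.346 to 0.977 CPM. Zfp57, a zinc finger protein that maintains genomic imprints, had a log2 fold change of -0.51 ± 0.07 (adjusted p = 3e-04), and Met, the receptor of hepatocyte growth factor, of -0.62 ± 0.10 (adjusted p = 0.0023). Aplnr, the apelin receptor, fell from 1.14 to 0.424 CPM. Ypel1 (-0.28 ± 0.05) and Dpysl3, a growth cone protein (-0.26 ± 0.05), fell as well. Spag6, Cd22 and Ypel1 overlap other gene models on the opposite strand. The call of Dpysl3 ended without 5 months control 4 (adjusted p = 0.054), and that of Ypel1 without 20 months control 1 or 3 (adjusted p = 0.05 in both, not past the threshold before rounding).

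The disease-associated microglia list rose with age in controls. Among its 17 tested members 5 rose over all genes tested and 13 adjusted over the list alone, 16 had a positive sign and the median log2 fold change was 0.43 (camera adjusted p = 1.1e-16, adjusted p = 0.024 with an estimated correlation). Its list mean was higher by 0.63 ± 0.11 (SE; exact permutation p = 0.0079, adjusted p = 0.13), above all younger libraries in 5 of 5 older ones. Itgax, the integrin CD11c, rose from 0.401 to 1.41 CPM (log2 fold change 1.78 ± 0.35), a call that ended without 5 months control 4 (adjusted p = 0.054). The 12 homeostatic microglia markers had a median of 0.08 and did not pass (adjusted p = 0.069), with 0 members called over all genes and 2 adjusted over the list alone, 1 in each direction. Complement rose with 2 of 14 members over all genes, C4b and C3, and 6 adjusted over the list alone (median 0.31, adjusted p = 2.7e-09, and 0.033 as the adjusted p with an estimated correlation). The list of inflammatory cytokines and NF-kB targets rose with 2 of 16 members over all genes and 7 adjusted over the list alone (median 0.33, adjusted p = 6.7e-07, and adjusted p = 0.024 with an estimated correlation). Its called members were Tlr2, a receptor of bacterial lipoproteins (0.63 ± 0.12), and Il33, a nuclear cytokine (0.41 ± 0.07). These were the 3 lists called with an estimated correlation.

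Interferon response and antigen presentation were higher at 20 months in controls. The interferon list rose with 3 of 28 members over all genes and 20 adjusted over the list alone, and all 28 had a positive sign (median 0.42, adjusted p = 2.6e-17, but adjusted p = 0.12 with an estimated correlation). Lgals3bp, which encodes galectin-3-binding protein, rose by 0.60 ± 0.10, and Ifit3, an interferon-induced protein, by 0.63 ± 0.14. The call of Ifit3 ended without 5 months control 1, 3, 4 or 5 (adjusted p = 0.053, 0.097, 0.1 and 0.12) and without 20 months control 2, 3 or 5 (adjusted p = 0.056, 0.075 and 0.06). MHC class I genes rose as a list, with 0 of 13 members over all genes and 11 adjusted over the list alone (median 0.6, adjusted p = 2.2e-11, adjusted p = 0.12 with an estimated correlation). B2m, the light chain of class I molecules, had a log2 fold change of 0.50 (adjusted p = 0.077) and H2-D1 of 0.53 (adjusted p = 0.078), and reads of the H2 genes may be shared. MHC class II rose with 0 of 7 members over all genes and 1 adjusted over the list alone (median 0.29, adjusted p = 0.018, adjusted p = 0.31 with an estimated correlation). Its members H2-DMb1 and Cd74 had log2 fold changes of 0.60 (adjusted p = 0.086) and 0.34 (adjusted p = 0.57). The call of this list ended without 5 months control 2 (adjusted p = 0.058), 20 months control 2 (0.052) or 20 months control 5 (0.12). Of the 5 older controls, 4 lay above all younger ones in the interferon list mean, 2 in MHC class I and 4 in MHC class II.

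Lysosome, reactive astrocyte and blood lists were also higher in the older controls. The lysosome list rose with Ctss, the protease cathepsin S, as the 1 of 19 members called over all genes (0.44 ± 0.08) and 8 adjusted over the list alone (median 0.09, adjusted p = 8e-07, adjusted p = 0.12 with an estimated correlation); Laptm5 had 0.16 (adjusted p = 0.14). Reactive astrocyte genes rose as a list, with 0 of 19 members over all genes and 9 adjusted over the list alone, 8 up and 1 down (median 0.32, adjusted p = 2.2e-05, adjusted p = 0.22 with an estimated correlation). Gfap, the intermediate filament of astrocytes, had a log2 fold change of 0.46 ± 0.11 (adjusted p = 0.067), and Serpina3n, a protease inhibitor, of 0.65 (adjusted p = 0.13). The erythrocyte list rose with 0 of 7 members over all genes and 5 adjusted over the list alone (median 0.46, adjusted p = 0.00061, adjusted p = 0.24 with an estimated correlation), and its members Alas2 and Fech, enzymes of heme synthesis, had 0.64 (adjusted p = 0.12) and 0.11 (adjusted p = 0.26). The B and plasma cell list rose with 0 of 7 members over all genes and 2 adjusted over the list alone (median 0.86, adjusted p = 7.2e-05, adjusted p = 0.12 with an estimated correlation). Its member Igkc, an immunoglobulin light chain, had 3.63 ± 1 (adjusted p = 0.15), with 23.3 CPM in 20 months control 2 and a group mean of 5.91 ± 9.78 CPM, and Ighg2c had 0.45 (adjusted p = 0.17). The lysosome list mean lay above all younger controls in only 1 of the 5 older ones. That number was 4 for reactive astrocytes, 3 for erythrocytes and 4 for B and plasma cells.

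Myelin, lipid and mitochondrial lists rose by small amounts in the older controls. Hapln2, a link protein of the matrix at nodes of Ranvier, rose by 0.33 ± 0.06 and was the 1 of 20 myelinating oligodendrocyte members called over all genes, with 6 adjusted over the list alone (median 0.06, adjusted p = 0.008, adjusted p = 0.24 with an estimated correlation). Aspa, an enzyme of oligodendrocytes, had 0.25 (adjusted p = 0.21), and the call of the list ended without 20 months control 5 (adjusted p = 0.14). Mitochondrially encoded mRNAs rose as a list with 0 of 7 members over all genes and 3 adjusted over the list alone (median 0.14, adjusted p = 0.00038, adjusted p = 0.32 with an estimated correlation). Their members mt-Nd1 (0.21) and mt-Co1 (0.14) did not pass. The share of counts on mitochondrially encoded genes was 4.46% in 20 months control 5 and 3.14% in 5 months control 1, the highest and the lowest of the 20 libraries. The call ended without 5 months control 1 (adjusted p = 0.062) and without both of these libraries (adjusted p = 0.35). Cholesterol biosynthesis (median 0.07, adjusted p = 0.0022, adjusted p = 0.32 with an estimated correlation) and the antioxidant list (median 0.05, adjusted p = 0.008, adjusted p = 0.12 with an estimated correlation) rose with 0 members over all genes and 1 each adjusted over the list alone. Insig1 (0.21), Lss (0.18), Nqo1 (0.28) and Gclm (0.11) did not pass, and the antioxidant call ended without 20 months control 5 (adjusted p = 0.061). Older controls with a list mean above all younger ones were 4 of 5 for myelinating oligodendrocytes and 3 for cholesterol biosynthesis. They were 2 for the antioxidant list and 1 for mitochondrially encoded mRNAs.

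At 20 months 6 lists were lower in controls. The oligodendrocyte precursor list fell with Gpr17 as the 1 of 15 members called over all genes and 2 adjusted over the list alone (median -0.07, adjusted p = 0.0094, adjusted p = 0.064 with an estimated correlation). Neu4, a sialidase, had -0.32 (adjusted p = 0.12). The neuroblast list fell with Sox11, a transcription factor of immature neurons, as the 1 of 17 called (-0.41 ± 0.08) and 5 adjusted over the list alone (median -0.11, adjusted p = 0.00061, adjusted p = 0.064 with an estimated correlation). Draxin, an axon guidance protein, had -0.83 (adjusted p = 0.068), and Dcx, a microtubule protein of migrating neuroblasts, had -0.06 and did not pass. The collagen list fell with 3 of 17 members over all genes and 6 adjusted over the list alone, 1 up and 5 down (median -0.10, adjusted p = 0.00034, adjusted p = 0.24 with an estimated correlation). Its called members were the fibrillar collagen genes Col1a2 (-0.47 ± 0.09), Col3a1 (-0.77 ± 0.16) and Col1a1, which was named after its value was seen (-0.66 ± 0.14). The call of Col3a1 ended without 5 months control 1, 3, 4 or 5 (adjusted p = 0.06, 0.074, 0.064 and 0.064) or 20 months control 3 (adjusted p = 0.095). Heat shock genes fell as a list, with Hsph1 as the 1 of 17 members over all genes and 2 adjusted over the list alone (median -0.11, adjusted p = 1e-05, adjusted p = 0.24 with an estimated correlation). Hsph1, a chaperone of the HSP110 family, had -0.23 ± 0.05 with an adjusted p of 0.05 that passed before rounding. The call of Hsph1 ended without any 1 of the 10 control libraries (adjusted p up to 0.19, without 5 months control 5) and Hspa8 did not pass (-0.19, adjusted p = 0.17).

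The glutamate receptor and postsynaptic density list (18 members, 1 with a positive sign, median -0.06) fell with an adjusted p of 0.0077, 0 members over all genes and 0 adjusted over the list alone. Its adjusted p was 0.52 with an estimated correlation and 0.52 without 20 months control 5, and its members Dlg4 (-0.09) and Shank3 (-0.11) did not pass. The endoplasmic reticulum stress list fell with 0 of 16 members over all genes and 7 adjusted over the list alone, 1 up and 6 down (median -0.09, adjusted p = 0.017, adjusted p = 0.53 with an estimated correlation). Calr (-0.21) and Pdia6 (-0.25), chaperones of that compartment, did not pass. The call ended without 5 months control 1 (adjusted p = 0.15) or 5 (0.27) and without 20 months control 3 (0.053) or 4 (0.063). Bdnf, Igf1, Vegfa, Fos, Arc and Ttr had log2 fold changes between ages in controls of -0.04, -0.06, 0.15, 0.11, -0.23 and -0.01 and did not pass. In all, 14 lists rose and 6 fell of the 48 with enough tested members, and 3 passed with an estimated correlation. At least 20 lists were given by 6 of 100 splits of the same libraries, the real one included. An exact permutation test of list means decides little here, since with a smallest p of 0.0079 at least 8 of the 48 lists must pass together or none can. The disease-associated microglia, inflammatory and neuroblast lists reached that p in controls (adjusted p = 0.13), and 0 lists passed for age in controls or for treadmill at either age.

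In treadmill animals, C3, Pcdhb9, Pcdhb14 and Mpeg1 were higher at 20 months than at 5 months. C3 rose 3.43-fold from 2.29 to 7.81 CPM (log2 fold change 1.78 ± 0.18, adjusted p = 4.5e-06), Pcdhb9 by 0.64 ± 0.06 (adjusted p = 4.5e-06), Pcdhb14 by 0.59 ± 0.07 and Mpeg1 by 0.52 ± 0.06. Gpr17 (-0.77 ± 0.12), Met (-0.61 ± 0.10), Aplnr (-1.47 ± 0.24) and Myoc, a secreted glycoprotein (31.3 to 21.5 CPM, adjusted p = 0.0045), fell. In each of these 8 genes all 5 older libraries lay beyond all 5 younger ones. In total 112 genes rose and 31 fell (143 genes; 100 and 31 with a proper symbol, 1947 at an unadjusted p under 0.05, which only the real split of 100 reached). Of these, 130 had no overlap between the ages, against 4% of all genes tested. Selection by p on the same libraries favors such genes, so this is no independent support. DESeq2 called 250 genes and limma-voom 135. The count was 83, 92 and 89 without 5 months treadmill 1, 2 and 5, and 81 and 66 without 20 months treadmill 4 and 5. It was 309 with only the groups compared, 552 with 1 surrogate variable, 415 without the 2 control libraries apart on the first component, and 0 from the values named RPKM.

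The genes called with age had the same sign in controls and treadmill animals. Of the genes called, 46 rose and 8 fell in both, where 0.41 and 0.04 were expected by chance, and all 173 genes called in either had the same sign in both (r = 0.89 across these genes, which are not independent replicates). The difference between the age effects is the treadmill effect differing between ages, and edgeR called 0 genes for it. A cohort or processing difference between the ages would also be shared by controls and treadmill animals, so the shared signs do not tell it from age.

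The disease-associated microglia list rose in treadmill animals with 8 of 17 members over all genes and 12 adjusted over the list alone (median 0.46, adjusted p = 3.1e-17, adjusted p = 0.019 with an estimated correlation). Complement (median 0.3, 3 of 14 over all genes, 7 adjusted over the list alone, adjusted p = 5.1e-10) and inflammatory genes (median 0.38, 3 of 16 over all genes, 8 adjusted over the list alone, adjusted p = 7.6e-08) rose as well, with an adjusted p of 0.024 and 0.019 with an estimated correlation. Reactive astrocyte genes rose with 5 of 19 members over all genes and 11 adjusted over the list alone (median 0.35, adjusted p = 1.4e-10, adjusted p = 0.065 with an estimated correlation). These 5 were Gfap, Serpina3n, Lcn2, Osmr and Aspg, named after their values were seen. Gfap had a log2 fold change of 0.73 ± 0.11 in treadmill animals (edgeR adjusted p = 0.0013) against 0.46 in controls, and the difference between these effects did not pass (adjusted p = 1). Interferon response (median 0.33, 2 of 28 over all genes, 14 adjusted over the list alone, adjusted p = 1.8e-12), MHC class I (median 0.47, 0 of 13 over all genes, 7 adjusted over the list alone, adjusted p = 8.6e-08) and lysosome (median 0.06, 1 of 19 over all genes, 4 adjusted over the list alone, adjusted p = 2.3e-05) rose. Their adjusted p values were 0.26, 0.34 and 0.26 with an estimated correlation. MHC class II (median 0.15, adjusted p = 0.35), B and plasma cell (median 0.41, adjusted p = 0.11) and erythrocyte lists (median 0.05, adjusted p = 0.99), which rose in controls, did not pass in treadmill animals. The difference between the age effects did not pass for MHC class II (adjusted p = 0.38) or B and plasma cells (0.094), and passed for erythrocytes (0.0014, but 0.89 with an estimated correlation).

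The lists of collagens (median -0.08, 2 of 17 over all genes, 4 adjusted over the list alone), oligodendrocyte precursors (median -0.04, 1 of 15, 4 adjusted over the list alone), neuroblasts (median -0.05, 1 of 17, 1 adjusted over the list alone) and heat shock genes (median -0.08, 0 of 17, 0 adjusted over the list alone) shifted downward in treadmill animals, each with an adjusted p of 0.015. Their adjusted p values were 0.71, 0.065, 0.23 and 0.74 with an estimated correlation. The collagen call ended without 5 months treadmill 2 (adjusted p = 0.053) or 20 months treadmill 1 (0.057), the neuroblast call without 5 months treadmill 3 (0.11), and the heat shock call without 5 months treadmill 4 (0.079), 5 months treadmill 5 (0.11) or 20 months treadmill 5 (0.19). In all 11 lists passed, and 17 without 20 months treadmill 2. With an estimated correlation 3 passed, and 36 of 100 splits of the same libraries, the real one included, gave at least 11 lists. By an exact permutation test of list means 8 passed (7 higher and 1 lower at 20 months), each at p = 0.0079, the smallest that splits of 5 and 5 libraries can give, and at an adjusted p of 0.048. For disease-associated microglia the list mean was higher by 0.72 ± 0.1 (SE) and in 5 of 5 older libraries, and the homeostatic list mean differed by 0.02 ± 0.05.

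**Figure D2:**
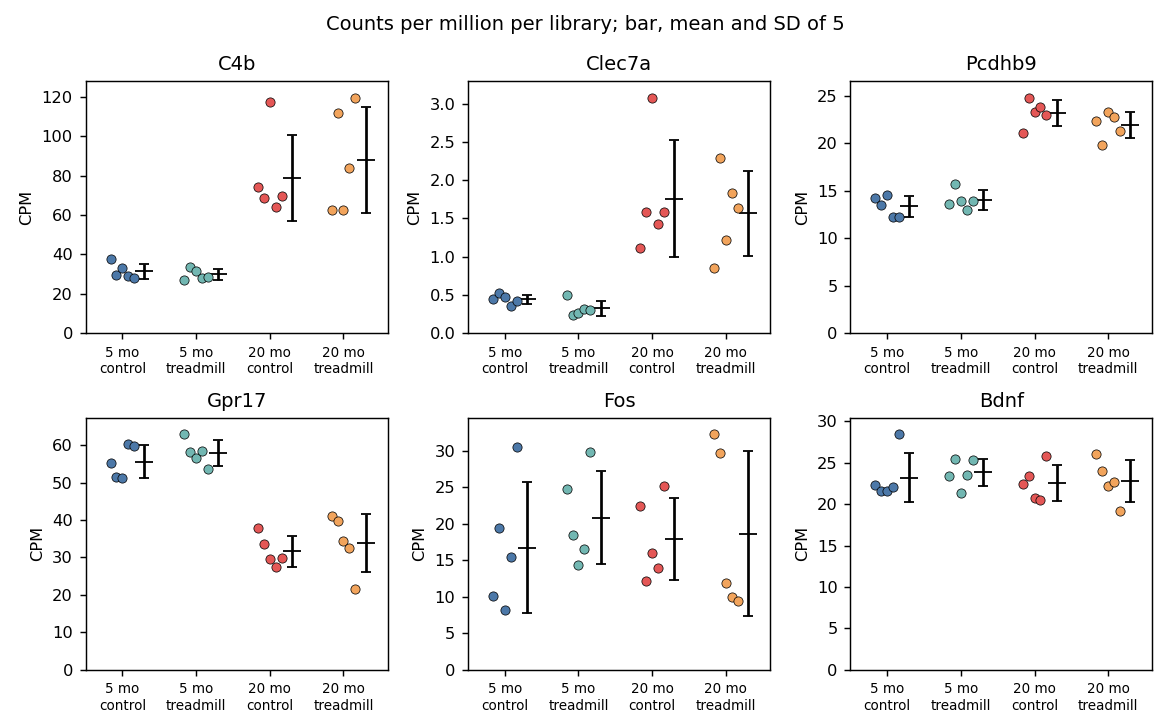
Points are CPM per library in the 4 groups of 5 for C4b, Clec7a, Pcdhb9, Gpr17, Fos and Bdnf, and bars give the mean and SD. C4b, Clec7a and Pcdhb9 are higher and Gpr17 is lower at 20 months, while Bdnf means are 23.2, 23.8, 22.6 and 22.8 CPM over the groups.

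Treadmill exercise at 5 months left the hemisphere transcriptome close to that of controls. Bdnf, the neurotrophin often measured after exercise, was at 23.2 CPM in controls and 23.8 CPM in treadmill animals, and the 95% interval of its fold change was 0.911 to 1.16. Vegfa, a growth factor of vessels, had an interval of 0.963 to 1.15, Igf1, insulin-like growth factor, of 0.841 to 1.12 and Dcx of 0.859 to 1.18. The immediate early genes Fos (16.7 and 20.8 CPM) and Arc (93.4 and 103 CPM) varied more, with intervals of 0.685 to 2.26 and 0.553 to 2.21. Ttr, the transthyretin of the choroid plexus, was at 633 and 531 CPM (interval 0.627 to 1.12), Gfap had an interval of 0.749 to 1.02 and C4b of 0.707 to 1.27. These are averages over brain hemispheres, so a change confined to a single region could be diluted in them.

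With edgeR, 0 of 17379 genes passed for treadmill at 5 months, with 391 at an unadjusted p under 0.05, a number that 72 of 100 splits of the same libraries reached (median of the other splits 580). DESeq2 and limma-voom also called 0. For 96.7% of the 14742 genes with a mean of at least 1 CPM the 95% interval lay within 1.5-fold, and for 99.7% within 2-fold. Among the smallest p values were those of Alas2, an enzyme of heme synthesis that overlaps Apex2 on the other strand (0.66 ± 0.17), Nhlh1, a transcription factor of developing neurons (1.10 ± 0.31), Ndufb4 (-0.34 ± 0.10) and Upf3b (-0.13 ± 0.04), each with an adjusted p of 1.

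Among the lists, 2 passed for treadmill at 5 months, erythrocytes and myelinating oligodendrocytes. Both had also risen with age in controls, against the same 5 months controls. At least 2 lists were given by 99 of 100 splits of the same libraries, the real one included. The erythrocyte list rose with 0 of 7 members over all genes and 5 adjusted over the list alone (median 0.54, adjusted p = 1.4e-05, adjusted p = 0.41 with an estimated correlation). Besides Alas2, it holds the alpha globin gene Hba-a2 (0.59 ± 0.19), whose reads may be shared with its paralogs. The share of counts on hemoglobin genes was 0.00403 ± 0.00107% in controls and 0.00581 ± 0.000909% in treadmill animals (SD, n = 5; exact permutation p = 0.032, adjusted p = 0.45 over 20 tests of library composition, where a measure can never pass alone). The myelinating oligodendrocyte list passed with a shift upward, while 0 of 20 members passed over all genes or adjusted over the list alone (median 0.09, adjusted p = 0.00018, adjusted p = 0.41 with an estimated correlation). Gjb1, a connexin of myelin, had 0.20 ± 0.06 and Mog, a myelin surface protein, 0.15 ± 0.05. Neurotrophic factors had a median of 0.03 (adjusted p = 0.19). Immediate early genes had a median of 0.12 (adjusted p = 0.067). The count of lists was 6, 10, 4 and 10 without 5 months treadmill 2, 3, 4 and 5, and 6, 6, 9, 8 and 6 without 5 months controls 1 to 5.

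Treadmill exercise at 20 months also moved single genes little. Bdnf was at 22.6 CPM in controls and 22.8 CPM in treadmill animals (95% interval of the fold change 0.902 to 1.15), Vegfa had an interval of 0.872 to 1.04, Igf1 of 0.897 to 1.19, Dcx of 0.923 to 1.27 and Gfap of 0.908 to 1.24. C4b, higher with age, was at 78.9 and 88.2 CPM (interval 0.849 to 1.47), and Ttr at 630 and 528 CPM (interval 0.627 to 1.12). Fos and Arc had intervals of 0.584 to 1.9 and 0.665 to 2.66. The edgeR test called 0 of 17379 genes, with 417 at an unadjusted p under 0.05 (87 of 100 splits reached it), and DESeq2 and limma-voom called 0. For 96.9% of genes with at least 1 CPM the interval lay within 1.5-fold and for 99.8% within 2-fold. The smallest p values belonged to Plekhg4 (0.37 ± 0.10), Slc10a3 (-0.36 ± 0.11), Cfap73 (0.82 ± 0.25), Ahnak2 (0.37 ± 0.11) and Ppp1r36 (-0.44 ± 0.14), each with an adjusted p of 0.98. Plekhg4 overlaps Kctd19 and Cfap73 overlaps Ddx54 on the other strand.

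At 20 months 11 lists passed for treadmill exercise, 4 up and 7 down, with 0 members called over all genes and 0 adjusted over the list alone in each. With an estimated correlation 0 passed. At least 11 lists were given by 75 of 100 splits of the same libraries, the real one included, so chance is not excluded for this count. The cerebellum list shifted upward, with 8 of 9 members positive (median 0.72, adjusted p = 0.00031, adjusted p = 0.96 with an estimated correlation). Pcp2, a Purkinje cell gene that overlaps Pet100, was at 0.278 and 1.45 CPM, and Cbln3, a granule cell gene, at 0.947 and 5.81 CPM. Over the 20 libraries Cbln3 ranged from 0.27 to 12.3 CPM. The list mean differed by 0.93 ± 0.56 (SE, exact permutation p = 0.14). An interval of 2 standard errors on each side ran from -0.19 to 2.04. The reactive astrocyte list shifted upward (median 0.12, adjusted p = 0.04, adjusted p = 0.96 with an estimated correlation), where Steap4 had 0.43 ± 0.19 and Lcn2 0.65 ± 0.34. This call ended without 20 months treadmill 2, 4 or 5 (adjusted p = 0.48, 0.19 and 0.21) or 20 months control 1 or 4 (adjusted p = 0.22 and 0.77).

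The lists of glutamate receptors and the postsynaptic density (median 0.06, adjusted p = 0.0094, with Gria3 at 0.11) and of nuclear long noncoding RNAs (median 0.11, adjusted p = 0.015, with Malat1 at 0.18 and Snhg11 at 0.11) shifted upward with treadmill at 20 months. Those of nuclear-encoded oxidative phosphorylation (median -0.06, 1 of 33 positive, adjusted p = 0.00025, with Ndufs3 at -0.13 and Sdhc at -0.10) and ribosomal proteins (median -0.08, 2 of 28 positive, adjusted p = 0.0091, with Rps2 at -0.13 and Rpl4 at -0.08) shifted downward. Their adjusted p values with an estimated correlation were 0.96, 0.96, 0.99 and 0.99. All 4 lists moved with 20 months control 5, which stood apart on the first component. Without it their adjusted p values were 0.74, 0.43, 0.86 and 0.89, and without it and 5 months control 1 they were 0.65, 0.25, 0.93 and 0.89. The glutamate call also ended without 20 months treadmill 2 (0.051) or 5 (0.07), the noncoding RNA call without 20 months treadmill 3 (0.054), 20 months treadmill 5 (0.26) or 20 months control 2 (0.069), and the ribosomal call without 20 months treadmill 1 (0.061).

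The cholesterol biosynthesis list shifted downward as a whole (median -0.07, 3 of 20 positive, adjusted p = 0.00028, adjusted p = 0.96 with an estimated correlation), with Dhcr7 at -0.11 and Mvd at -0.22. The choroid plexus list shifted downward (median -0.15, 2 of 17 positive, adjusted p = 0.00031, adjusted p = 0.96 with an estimated correlation), with Folr1, a folate receptor, at -0.31 and Slc4a5, a bicarbonate transporter, at -0.26, and this call ended without 20 months treadmill 5 (adjusted p = 0.65). So did the ependymal list (median -0.13, adjusted p = 0.015, adjusted p = 0.96 with an estimated correlation), with Cfap126 at -0.42 and Ccdc153 at -0.36. That call ended without 20 months treadmill 5 (adjusted p = 0.81) or 20 months control 1, 3 or 5 (0.061, 0.065 and 0.056), and with the choroid plexus list as a covariate (0.67). The hypothalamus list shifted downward (median -0.16, adjusted p = 0.0035, adjusted p = 0.96 with an estimated correlation), with Sim1 at -0.38 and Trh at -0.16, a call that ended without 20 months treadmill 2 (0.1) or 20 months control 5 (0.075). The B and plasma cell list shifted downward (median -0.36, adjusted p = 0.02, adjusted p = 0.96 with an estimated correlation), with Igkc at -1.83 ± 0.80 and Ighg2c at -0.32. It was lost without 20 months control 2 (adjusted p = 0.72), the library with 23.3 CPM of Igkc, and without 20 months control 3 (0.059) or 20 months treadmill 2, 3 or 4 (0.085, 0.15 and 0.057). The count of lists was 6 without 20 months treadmill 5 and 7 without 20 months control 5.

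**Figure D3:**
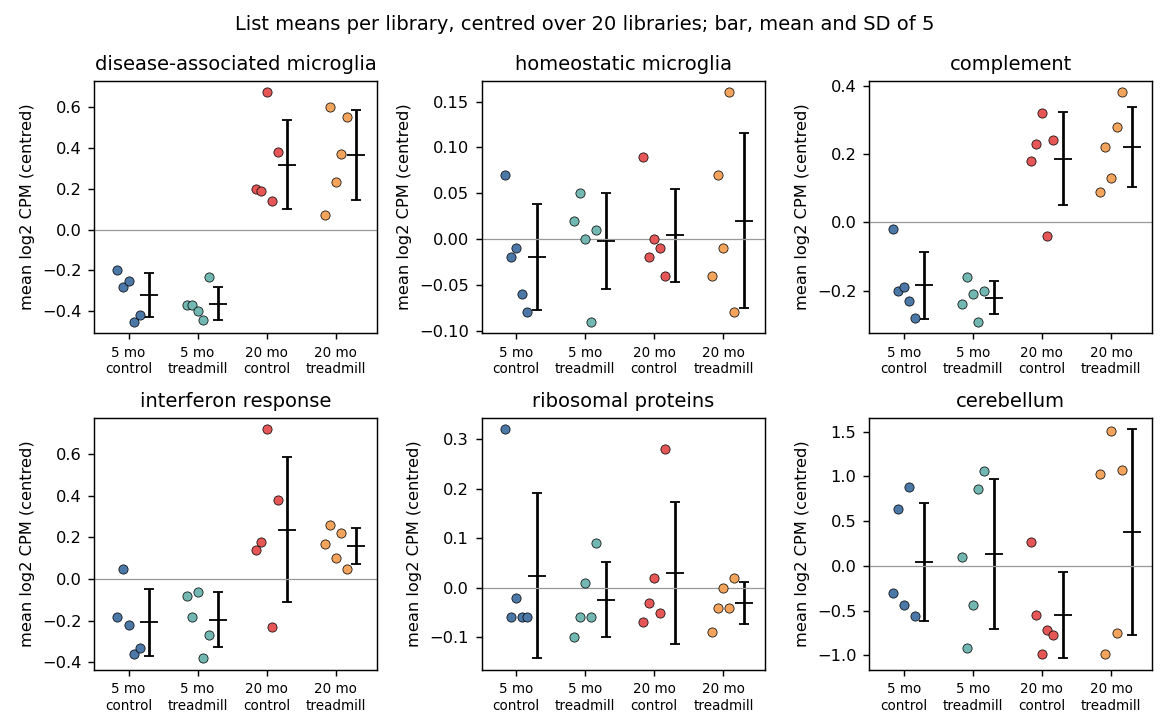
Points are list means per library (log2 CPM of the members, each centered over the 20 libraries) in the 4 groups of 5 for 6 gene lists, and bars give the mean and SD. Disease-associated microglia means run from -0.32 and -0.36 at 5 months to 0.32 and 0.36 at 20 months, homeostatic means stay between -0.02 and 0.02, and the cerebellum means have SDs of 0.48 to 1.15.

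Averaged over both ages, 0 genes and 9 lists passed for treadmill exercise, and 59 of 100 splits of the same libraries gave as many lists. The edgeR test called 0 of 17379 genes, with 592 at an unadjusted p under 0.05 (42 of 100 splits reached it), and DESeq2 and limma-voom called 0. The smallest p values were those of Plekhg4 (0.31 ± 0.07), Pnma1 (-0.30 ± 0.07), Rad21l (-0.53 ± 0.14), Cfap73 (0.66 ± 0.17) and Homer3, a postsynaptic scaffold (0.18 ± 0.05), each with an adjusted p of 0.97. Erythrocyte (median 0.31, adjusted p = 0.0051, 2 members adjusted over the list alone), cerebellum (0.39, adjusted p = 0.012), glutamate receptor (0.04, adjusted p = 0.002) and nuclear noncoding RNA lists (0.07, adjusted p = 0.015) shifted upward, each with an adjusted p of 0.88 with an estimated correlation. Choroid plexus (median -0.15, adjusted p = 0.00027), hypothalamus (-0.14, adjusted p = 0.0051) and cholesterol lists (-0.03, adjusted p = 0.0074) shifted downward, with an adjusted p of 0.88 each, and oxidative phosphorylation (-0.04, adjusted p = 0.0013) and ribosomal lists (-0.07, adjusted p = 0.002), with an adjusted p of 0.96 each, with an estimated correlation. Members called over all genes were 0 in all 9, and outside the erythrocyte list 0 adjusted over the list alone. The glutamate, noncoding RNA, hypothalamus and ribosomal calls ended without the 2 libraries apart on the first component (adjusted p = 0.62, 0.57, 0.066 and 0.11), and the oxidative phosphorylation list turned positive (0.02). The oxidative phosphorylation and ribosomal calls also ended without 5 months control 1 (adjusted p = 0.32 in both) or 20 months control 5 (0.36 and 0.2). The cerebellum call ended without 5 months treadmill 5 (0.087), 5 months control 3 or 5 (0.057 in both), 20 months treadmill 3 (0.13) or 20 months control 3 (0.051), which also ended the cholesterol call (0.063). The noncoding RNA call ended without 5 months treadmill 1 (0.06), 5 months control 1 (0.086), 20 months treadmill 5 (0.12) or 20 months control 2 or 5 (0.051 and 0.084).

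The treadmill effect differed between the ages for 0 genes by edgeR, DESeq2 or limma-voom, with 297 at an unadjusted p under 0.05 (95 of 100 splits reached it). Spaca9 (-1.58 ± 0.42), Zfp626 (0.33 ± 0.10), Terf1 (0.31), Calhm5 (0.36) and Nek11 (-0.51) had the smallest p values, all with an adjusted p of 1. For 6 lists the difference passed, with a mean difference of -0.35 for erythrocytes (adjusted p = 0.0014), -0.09 for myelinating oligodendrocytes (0.0011), 0.19 for reactive astrocytes (0.019), 1.01 for the cerebellum (0.019), -0.10 for mitochondrially encoded mRNAs (0.019) and -0.05 for cholesterol biosynthesis (0.019). Their adjusted p values with an estimated correlation were 0.89, 0.76, 0.89, 0.89, 0.89 and 0.89, and 0 members were called over all genes. At least 6 lists were given by 88 of 100 splits of the same libraries, the real one included. The count of lists was 3 without 5 months treadmill 2 or 20 months treadmill 2, and 13 without 20 months control 4. The erythrocyte and myelinating oligodendrocyte calls held without each library in turn. They share the 5 months controls with the age rise in controls and the treadmill rise at 5 months, so these are not independent results. The erythrocyte list mean was -0.3 in 5 months controls and 0.12 in 5 months treadmill animals. At 20 months it was 0.07 in controls and 0.11 in treadmill animals. For myelinating oligodendrocytes the means were -0.05, 0.02, 0.03 and 0.01 in the same order. The reactive astrocyte call ended without 5 months treadmill 2 (adjusted p = 0.12), 5 months control 1 (0.16), 20 months treadmill 2 or 4 (0.19 and 0.064) or 20 months control 1 or 4 (0.097 and 0.29). The cerebellum call ended without 5 months treadmill 2 (0.14), 5 months control 1, 2 or 4 (0.055, 0.084 and 0.094), 20 months treadmill 1 or 3 (0.053 and 0.16) or 20 months control 3 (0.078). The mitochondrial call ended without 5 months treadmill 1 (0.23), 5 months control 1 (0.65), 20 months treadmill 2 (0.069) or 20 months control 5 (0.22), and the cholesterol call without 5 months treadmill 2 (0.099), 5 months control 1 (0.053), 20 months treadmill 2 or 4 (0.078 and 0.063) or 20 months control 3 (0.14).

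The treadmill effect at 20 months did not run against the age effect beyond chance. The 20 months controls were split so that the effects shared no library. The correlation across 17379 genes was then 0.06 (exact permutation p = 0.54, central 95% of permuted values -0.17 to 0.16), and genes are not independent replicates. With shared controls it was -0.36, and the permuted mean with shared controls was -0.4 (exact permutation p = 0.7). The treadmill effects at 5 and 20 months had a correlation of 0.13 across genes (exact permutation p = 0.51 over 63504 splits, central 95% of permuted values -0.28 to 0.28), and of -0.06 without 5 months control 1.

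The other 21 of the 48 lists passed in none of the 6 comparisons. They held markers of cortical excitatory neurons, interneurons, striatal neurons, hippocampus, thalamus and olfactory bulb, of astrocytes, endothelial cells, pericytes and meningeal fibroblasts, and of homeostatic microglia. They also held presynaptic, neurotrophic, immediate early, circadian, glucocorticoid-responsive, angiogenesis, mitochondrial biogenesis, proliferation, histone and senescence genes. The smallest adjusted p among their camera tests was 0.063, for immediate early genes with treadmill averaged over ages. The lists of T and NK cells, neutrophils and the pituitary had 4, 4 and 1 tested members and were not tested, with highest group means of 7.9, 3.18 and 1.73 CPM.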

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

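The tests of depth, unspliced RNA, treadmill exercise on the cerebellum list, microglia and blood, and the splits for the ages and for treadmill at each age, were chosen after the results were seen; the tests of transcript length and of cerebellar tissue and the splits for the treadmill average and the difference between ages were written before. A value was listed where a library lay so far from the other 4 of its group that the gap, as a part of the group's range, exceeded 0.71, or where the treadmill effect on a list differed between the ages. Chance gives about 1 in 20 groups, or 26.6 of the 532 groups examined, and 50 were found. Of these 11 fell on 5 months control 1, 10 on 20 months control 5, 6 each on 20 months control 3 and 20 months treadmill 5, and 3 on 5 months control 5. Values in parentheses are that gap ratio.

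On the first component 5 months control 1 (0.9) and 20 months control 5 (0.849) stood above their groups, at 32.8 and 39.9. The same libraries stood apart in nuclear-encoded oxidative phosphorylation genes (0.817 and 0.94) and ribosomal protein genes (0.91 and 0.734), both high, and in glutamate receptor genes (0.791 and 0.791), low. A difference in depth does not account for it, since the total counts of 2 of the 2 libraries lay inside the range of the other 18. The loading of a gene fell with its exonic length (Spearman rho -0.5 over 17326 genes), and the share of counts on unconfirmed, mostly unspliced gene models was 0.0581% at most in the 2 libraries against 0.061 to 0.0749% in the others. Both could come from a difference in RNA quality or in library preparation, which may have favored short, spliced transcripts. The 2 libraries lay at opposite ends in the share of counts on mitochondrially encoded genes. It was 3.14% in 5 months control 1, the lowest of all libraries, and 4.46% in 20 months control 5, the highest. The libraries belong to different groups, and no biological explanation was tested.

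The cerebellum list, higher with treadmill at 20 months and different between the ages (mean difference 1.01, adjusted p = 0.019), lost both calls with an estimated correlation (adjusted p = 0.96 and 0.89), and varied strongly within groups. After group means were removed, 94.1% of the variance of its members lay on 1 component, and Gabra6 ran from 0 to 6.62 CPM and Fat2 from 0.435 to 16.8 CPM over the libraries. This is consistent with uneven amounts of cerebellar tissue left on the hemispheres at dissection. An effect of treadmill exercise cannot be told apart from it, since the list mean had an exact permutation p of 0.14 between the groups at 20 months and its interval was wide. Calb1, a member that forebrain neurons also express, varied less (127 to 157 CPM).

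The rise of disease-associated microglia genes with age may reflect a changed state of these cells. A larger number of microglia as the whole cause is argued against by the homeostatic list mean, which differed by 0.02 between the control groups, while the disease-associated mean differed by 0.63 ± 0.11 (SE). Residual blood as the whole cause is argued against in treadmill animals, where the erythrocyte list mean differed by 0 ± 0.12 between the ages and the disease-associated mean by 0.72 ± 0.1. In controls, where the erythrocyte mean differed by 0.37 ± 0.17, it is argued against by treadmill at 5 months, which came with an erythrocyte difference of 0.41 ± 0.15 and a disease-associated difference of -0.04 ± 0.06. Blood of another composition in older animals, or a loss of homeostatic transcripts per cell that offsets more cells, was not tested, and other cells carrying the same transcripts stay open.

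For the age comparisons, chance alone is an unlikely source of the counts of genes past the adjusted threshold. The smallest share that 100 splits can give is 1 in 100, and these splits were chosen after the results were seen. They cannot tell age from another difference between the same groups. For the count at an unadjusted p under 0.05 in controls, which 32 of 100 splits reached, chance is not excluded. Among 100 splits of the same libraries, 1, the real split, gave as many as 84 genes in controls (highest other 5) and 1 as many as 143 in treadmill animals (highest other 1). For the counts of lists chance is not excluded either. At least 20 lists were given by 6 of 100 splits in controls (highest other 21), and at least 11 by 36 in treadmill animals (highest other 19). Every split gives at least 0 genes, so the splits decide nothing for counts of 0, which 100 of 100 splits match for treadmill at 5 months (highest other 1), at 20 months (highest other 0), averaged (highest other 1) and differing between ages (highest other 1). For the lists of these comparisons chance is not excluded. As many were given by 99 splits for treadmill at 5 months (2 lists, highest other 13), 75 at 20 months (11, highest other 21), 88 for the difference between ages (6, highest other 18) and 59 for the average (9, highest other 18).

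Besides the cerebellum, the treadmill effect differed between the ages in erythrocyte (-0.35), reactive astrocyte (0.19), myelinating oligodendrocyte (-0.09), mitochondrially encoded (-0.1) and cholesterol lists (-0.05), by a test of the difference itself that 0 lists passed with an estimated correlation. On the second component 5 months control 5 was low (0.724) and 20 months control 3 (0.72) and 20 months treadmill 5 (0.74) were high, and on the third 5 months control 5 (0.736) and 20 months control 3 (0.805) were high. Total counts were high in 20 months treadmill 1 (0.779). In 20 months control 5 the mitochondrially encoded share (0.864), the share of the 10 most abundant genes (0.955), the mitochondrially encoded list (0.921) and mt-Nd1 (0.854) were high, and Lss was low (0.761). In 5 months control 1 the nuclear noncoding RNA list was low (0.778), with Snhg11 (0.817), and the antioxidant (0.837) and lysosome lists (0.814), Gfap (0.739) and H2-DMb1 (0.728) were high. Rpl4 was high (0.749 and 0.752) in 5 months control 1 and 20 months control 5. In 20 months control 3, C4b (0.751), Cd22 (0.752) and Serpina3n (0.765) were high and Aspa was low (0.777). In 20 months treadmill 5, Ighg2c (0.877) and Lss (0.739) were high, and Ccdc153 (0.843), Ypel1 (0.86) and Col3a1 (0.803) were low. Low values were also those of reactive astrocytes in 5 months treadmill 2 (0.887), MHC class II in 20 months control 4 (0.715), collagens in 5 months treadmill 4 (0.716), Upf3b in 20 months treadmill 2 (0.783), Gjb1 (0.748) and Hapln2 (0.808) in 5 months treadmill 1, Hapln2 in 20 months control 1 (0.759), Ccdc153 (0.737) and Itgax (0.747) in 5 months control 4, Draxin in 20 months treadmill 3 (0.78) and Terf1 in 20 months control 2 (0.782). Bdnf in 5 months control 5 (0.876), Ppp1r36 in 5 months treadmill 5 (0.778) and B2m in 20 months treadmill 4 (0.847) were high.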

How the results depend on the processing

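The settings without the 2 control libraries apart on the first component and with the cerebellum covariate were chosen after the data were seen, and the others were planned. Genes called for the 4 treadmill comparisons stayed at 0 in every setting run, and the DESeq2 scaling moved the median of all genes by at most 0.002. For age in controls the count of 84 became 162 with the DESeq2 Wald test, 30 with only the groups compared, 391 with 1 surrogate variable, and 3, 2 and 0 from the values named RPKM (limma trend, pseudocount 1, no filter). For age in treadmill animals 143 became 250, 309 and 552, then 0, 0 and 0, and 415 without the 2 libraries. The surrogate variable followed the first component (absolute r = 1), and its calls held 84 of 84 and 142 of 143 of the genes. Without the 2 libraries, 66 and 141 of them were shared. The RPKM settings take values that were mostly not divided by their own library total, by the construction of that table. For the rest the cause was not tested.

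Lists fell to 0, 0, 3, 3, 0 and 0 with an estimated correlation (treadmill at 5 and 20 months, age in controls and in treadmill animals, difference between ages, average), which widens the test by construction. Lists for treadmill at 5 months became 10 with the stricter filter, 4 with the choroid plexus covariate and 4 without the 2 libraries. At 20 months they became 7 with 1 surrogate variable, 6 with the choroid plexus covariate and 7 without the 2 libraries. The difference between ages gave 2 without a filter. The correlation of age and treadmill effects was -0.36 with shared controls, where the shared libraries alone gave a permuted mean of -0.4. Reversed were Dpysl3 (0.25, 0.23 and 0.25) and Hsph1 (0.25, 0.25 and 0.25) in the 3 RPKM settings, whose values were mostly not divided by their own library total. So was the oxidative phosphorylation list of the treadmill average (0.02 without the 2 libraries). Those 2 controls had list means of 0.223 and 0.25, against at most -0.021 and -0.0159 in the other controls of their groups, so leaving them out lowers the control means. For the other changes the cause was not tested.

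Leaving out 1 library gave 47 (without 5 months control 4) to 113 genes for age in controls, 66 (without 20 months treadmill 5) to 152 for age in treadmill animals, and lists of 2 to 10, 6 to 15, 20 to 23, 11 to 17, 3 to 13 and 8 to 13 in the order above. The 2 correlations ran from -0.03 to 0.11 and from -0.06 (without 5 months control 1) to 0.18. Of 35 named age calls 29 held in each such setting and 22 in every other setting outside the RPKM values. Over all named genes, 1309 values in the other settings kept their side, 121 were weaker, 22 stronger and 60 moved, and of the list values 375 kept their side and 89 were weaker. Without 1 library, 1341 gene values kept their side, 26 were weaker, 11 stronger and 2 moved, and 659 list values kept their side and 81 were weaker. The composition tests kept their side in 20 and 200 values, which says little, since with a smallest p of 0.0079 over 20 tests a measure can never pass alone. At these depths genes near the filter were the least certain, with 46% of the smallest simulated changes recovered over all genes and 65.7% above 2 CPM.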

Other observations

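The protocadherin clusters were chosen for description after the values of their genes were seen, so a test of a cluster as a whole is not independent of that choice. Of the 22 tested beta protocadherins, neuronal cell adhesion genes that lie side by side on chromosome 18 between 37264938 and 37524479, 7 rose with age in controls and 8 in treadmill animals, and 0 fell. The rise was not shared by all members, with a positive sign in 21 in controls and in 17 in treadmill animals, and medians of 0.26 and 0.38. The log2 fold changes of Pcdhb15 to Pcdhb22 ran from -0.03 to 0.26 in controls and from -0.21 to 0.15 in treadmill animals, and none of these 8 genes was called. In an exact permutation test of the mean of the 22 genes on the log2 CPM scale, the difference between ages was 0.35 in controls (p = 0.016) and 0.32 in treadmill animals (p = 0.0079), and that of treadmill exercise was 0.05 at 5 months (p = 0.56) and 0.01 at 20 months (p = 0.87), unadjusted. With the choice made after the values, the small p values for age add nothing to the calls of single genes. Treadmill exercise called 0 members. The neighboring alpha cluster (12 tested, medians -0.05 and -0.02) had 0 genes called, and the gamma cluster (20 tested, medians 0.09 and 0.1) had 1 in controls and 1 in treadmill animals. Sharing of reads between these similar genes was not tested.

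Outside the rule for named genes, and named after their values were seen, a few genes of other groups passed with age. Neat1, a nuclear noncoding RNA of paraspeckles, rose by 0.37 ± 0.07 in controls and 0.35 ± 0.07 in treadmill animals (SE; edgeR adjusted p = 0.0047 and 0.0064). Top2a, a topoisomerase of dividing cells, fell by 0.97 on the log2 scale in treadmill animals (edgeR adjusted p = 0.014), and Sox4, a transcription factor of immature neurons, fell by 0.49 there (edgeR adjusted p = 0.015). The proliferation list, which holds Top2a, passed in no comparison. Its mean differed between ages by -0.14 ± 0.06 in controls and -0.13 ± 0.05 in treadmill animals (SE). Sox4 was not called in controls, where Sox11 was the only neuroblast member called. Cst7, the protease inhibitor cystatin F of microglia, rose by 2.71 ± 0.50 in treadmill animals (edgeR adjusted p = 0.007) from 0.0899 to 0.616 CPM, and had 1.37 ± 0.49 in controls (adjusted p = 0.278), and the difference between these effects did not pass (0 genes called).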
